A study of Homo sapiens with 4 samples.

How the data were processed

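Total RNA from 4 samples of the HCCLM3 liver cancer line was profiled on Affymetrix Human U133 Plus 2.0 arrays, 1 array per sample. These are 1-colour arrays on which biotin-labelled cRNA, primed from the poly-A tail, binds short probes that mostly lie near the 3′ end of each transcript. Per the labels' protocols, cells were first sorted magnetically by EpCAM. Mimics were then transfected with a lipid reagent into EpCAM-negative cells, and the cholesterol-conjugated antagomir was added to the medium of EpCAM-positive cells. RNA integrity was inspected before labelling, per the labels' protocols, and the integrity values were not used here.

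The deposited values are log2 signals of the MAS5 algorithm, which is named in the submitters' processing notes. The MAS5 version, the target level and any detection calls are not given in the sources used here. The log base and the scaling were settled from the values: with the log2 undone, the mean after trimming 2% at each end was 500.1 on each of the 4 arrays. The arrays had therefore been scaled by the authors to a common trimmed mean, and no other scaling was applied. Some values are exactly 0, which is the lowest value on each array. Their number was 174 on the NC mimic array, 236 on the miR-429 mimic array, 150 on the NC antagomir array and 249 on the antagomir-429 array.

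Each array holds 54675 probe sets, of which 62 are Affymetrix controls and were left out of all gene counts. The platform annotation, which can be old, gave 1 gene symbol for 41097 probe sets and several for 1801. A further 11777 probe sets, controls among them, were not in that table and stayed unnamed. Entrez identifiers of 41043 single-gene probe sets matched the RefSeq gene table of assembly GRCh38.p14, 54 did not, and 0 symbols changed. No genome build is named for the series, so that table was used only for names and for the length of each gene's span, and no coordinates are given.

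A gene was represented by its brightest single-gene probe set, that with the highest mean log2 signal over the 4 arrays, which gave 19775 genes. A gene counted as expressed when that mean was at or above the median over all 54613 non-control probe sets, a log2 signal of 5.73 or a signal of 52.9, which left 13180 genes. This level is called the floor. A stricter filter at the 75th percentile, a signal of 265.6, left 8130 genes. Differences are log2 ratios between single arrays, and genes at or past 2-fold were counted. No offset was added to the signals. A fold against an array under the floor was taken against the floor and is given as "at least".

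With 1 array per group there is no residual spread to test against, so no p-value, standard error or false discovery rate was computed. The 3 comparisons were the miR-429 mimic over the NC mimic, antagomir-429 over the NC antagomir, and the EpCAM-positive NC antagomir array over the EpCAM-negative NC mimic array. The first pair of comparisons shares no array. The third shares a control array with each of them, so its values are not independent of theirs. The overlap of genes past 2-fold was set beside the number expected from independent lists, and beside the number expected when genes are matched on signal in 20 bins.

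There were 17 gene lists, fixed before the data were examined together with the comparisons, the filters and the rule for naming genes. They cover published targets of miR-429, miR-200b and miR-200c, which share a seed, an RBBP4 axis of RBBP4, E2F1 and POU5F1, the chromatin complexes that contain RBBP4, E2F targets and DNA replication, mitosis, CDK inhibitors and p53 targets, epithelial genes, mesenchymal genes, and markers of liver tumour-initiating cells and pluripotency. The others are hepatocyte genes, the interferon response, NF-kB and inflammatory genes, sterol synthesis and uptake, the unfolded protein and integrated stress response, hypoxia and glycolysis, the small RNA machinery, and markers of leukocytes and stroma as cell types other than the line. For each list the median log2 ratio of its expressed members is given with its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. These percentiles describe these arrays and are not tests. The RBBP4 axis was too short for a percentile.

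Genes were named by a fixed rule. EPCAM, RBBP4, E2F1, POU5F1, ZEB1 and ZEB2 were always named. For each comparison, the rule took the 10 genes with the largest log2 ratio in each direction among those at or above the floor on both arrays, and the 3 in each direction whose dimmer array lay under the floor. It also took up to 10 genes in each direction that were past 2-fold in opposite directions with the mimic and the antagomir, and up to 4 members of each list past 2-fold. Where no member of a list was past 2-fold, its 2 largest could be given. Genes outside this rule are marked as chosen after their values were seen.

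The alternatives were median centring, quantile normalization, an offset of 13.1 signal units before log2 (the 20th percentile of signals), the median over a gene's probe sets, no filter, the stricter filter, and a 1.5-fold threshold. After the data were seen, 2 more were added: subtraction of the running median of the log2 ratio over gene span, in 50 bins, and the EpCAM-positive NC antagomir array in place of the NC mimic array. A planned search for miR-429 seed sites needed 3′ UTR sequences, which were not used here.

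The counting of genes past 2-fold was tested on simulated data, with noise set to the robust spread seen in each comparison, 13180 genes and 200 of them changed. That spread also holds any true changes and array differences, and it was drawn as normal. Without replicates the noise itself is unknown, so the numbers of unchanged genes that passed are not a false-positive rate. With the spread of the mimic comparison, 49.5% of 2-fold changes, 95.5% of 4-fold changes and 99.5% of 8-fold changes were counted, while 1027 to 1044 unchanged genes also passed 2-fold. With the spread of the antagomir comparison these shares were 51.0%, 96.5% and 100.0%, and 774 to 795 unchanged genes passed. A change set at the threshold itself passes or fails by the sign of the noise, so the shares for 2-fold do not depend on the spread. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.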

Results

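Gene expression was measured in HCCLM3, a human hepatocellular carcinoma cell line, after sorting for EpCAM, an epithelial adhesion molecule that also serves as a surface marker of liver tumour-initiating cells. The 4 samples formed 4 groups of 1 array each. EpCAM-negative cells received 100 nM of a miR-429 mimic, a synthetic duplex that supplies the mature microRNA, or 100 nM of a negative-control (NC) mimic. EpCAM-positive cells received 40 µM of antagomir-429, an antisense RNA that blocks miR-429, or 40 µM of an NC antagomir. Treatment lasted 4 days. miR-429 belongs to the miR-200 family, whose textbook targets are the transcriptional repressors ZEB1 and ZEB2. The title of the series gives the identification of miR-429 targets as its aim, and a target would be lower with the mimic and higher with the antagomir.

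The arrays had been scaled to a common trimmed mean signal of 500.1, and their median signals lay between 62.7 and 67.1. Between 54.2% and 55.9% of probe sets were at or above the floor on each. Because each group had 1 array, none of the differences given here has a replicate check, and the number of arrays limits the precision. How far single genes scattered depended on their brightness. With the expressed genes in 4 equal bins by signal, the robust SD of the log2 ratio in the dimmest bin was 0.82 with the mimic and 0.79 with the antagomir. In the brightest bin it was 0.36 and 0.15.

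EPCAM itself was higher in EpCAM-negative cells given the miR-429 mimic. Its only probe set had a signal of 3838 with the miR-429 mimic and 1106 with the NC mimic, a log2 ratio of 1.80 or 3.47-fold. NF-kB and inflammatory genes were higher as a group, with 15 of 16 expressed members above 0 and a median log2 ratio of 0.47. RBBP4, a histone-binding subunit of several chromatin complexes that was named in advance because of its reported link to miR-429 in liver cancer, was not lower, with a signal of 6884 against 4845 (log2 ratio 0.51) by its brightest probe set. Of the other RBBP4 probe sets past the filter, 1 was lower (signals 252 and 353, -0.49) and the dimmest had 2.21. The published targets of miR-429 and of miR-200b and miR-200c, which share its seed, were not lower as a group either, with a median of 0.16 over 37 expressed members of 48. Protein was not measured, and uptake or activity of the mimic was not checked here. These mRNA signals therefore do not settle whether RBBP4 is a target.

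Among the lists that stood apart from random lists of like signal, the small RNA machinery had the highest median, 0.63 over 13 expressed members (percentile 99.98). In it AGO3, an Argonaute protein, was at least 3.5-fold higher, with the NC mimic array under the floor. The microRNA-processing nuclease DROSHA had 1.30 and the silencing scaffold TNRC6A 1.15. The NF-kB list lay at percentile 99.82. Its members past 2-fold were LCN2, an iron-siderophore binding protein of inflammation (1.32), and TNFAIP3, a feedback inhibitor of NF-kB (1.08). Markers of liver tumour-initiating cells and pluripotency had a median of 0.33 over 17 expressed members (percentile 99.34), and EPCAM was the only one past 2-fold. The unfolded protein and integrated stress response had a median of 0.17 over 20 members (percentile 97.91), with CHAC1, a glutathione-degrading enzyme induced by ATF4, at 1.23. Markers of leukocytes and stroma had a median of 0.58 over 10 expressed members (percentile 98.89), but those past 2-fold were dim: VWF, an endothelial protein, had signals of 126 and 37, and the T cell gene CD3E had 136 and 55. With the median over probe sets this list lay at percentile 61.79, and the stress response at 93.64. With the EpCAM-positive NC antagomir array as the control, an alternative added after the data were seen, the small RNA list lay at percentile 89.64 and the tumour-initiating list at 79.95, while the NF-kB list lay at 100.0. That control also put the hypoxia list at a median of 0.48 (percentile 100.0), the mitotic list at 0.29 (percentile 99.96) and the sterol list at 0.29 (percentile 99.98), all within the range of random lists with the NC mimic array as control. But that control itself differed from the NC mimic array in these lists. Its median over the NC mimic array was -0.49 for NF-kB, -0.48 for hypoxia, -0.19 for mitotic and -0.15 for sterol genes. It was 0.31 for the small RNA machinery and 0.16 for tumour-initiating markers. Such differences alone shift the values, so this control does not settle which lists hold.

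Epithelial genes had no common direction. Of 23 expressed members 5 were at least 2-fold higher and 0 were lower, and the median was 0.05 (percentile 79.79). After EPCAM, the highest were the tight-junction scaffold TJP1 (1.37), the desmosomal plaque protein DSP (1.35) and the tricellular junction protein MARVELD2 (1.10). Mesenchymal genes had a median of 0.08 over 29 members (percentile 78.74). There, 3 members were past 2-fold and all were higher: the microfibril protein FBN1 (1.52), the repressor SNAI1 (1.23) and N-cadherin, CDH2 (1.14). With the EpCAM-positive NC antagomir array as control none of the 6 genes named after EPCAM was past 2-fold: TJP1 had -0.07, DSP 0.46, MARVELD2 0.56, FBN1 0.19, SNAI1 0.57 and CDH2 0.39. EPCAM stayed past 2-fold there (1.64). So did PRSS8, the remaining epithelial member past 2-fold (signals 197 and 82), and MAL2 became so (710 and 234). PRSS8 and MAL2 were chosen after their values were seen. The epithelial median with that control was 0.15 (percentile 94.2), within the range of random lists. ZEB1 was dim, with a signal of 91 with the miR-429 mimic and 80 with the NC mimic, and 0 of 5 probe sets of ZEB2 passed the filter. NCAM1, a neural adhesion molecule with an NC mimic signal of 44, was the only published target past 2-fold as measured, and it was higher, by at least 1.8-fold against the floor.

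The cell-cycle lists lay within the range of random lists. E2F1 had a log2 ratio of -0.31 by its brighter probe set and -0.06 by the other. E2F targets and DNA replication had a median of 0.00 (percentile 80.39), with 0 of 34 members past 2-fold. The 2 largest there were RBL1, a pocket protein (-0.99), and the replication factor MCM10 (0.80). Mitotic genes had a median of 0.10 (percentile 87.01), with the spindle checkpoint kinase TTK at -1.10. CDK inhibitors and p53 targets had a median of -0.22 (percentile 9.04), with the ribonucleotide reductase subunit RRM2B at -1.04. CDKN2B was at least 1.8-fold higher from an NC mimic signal under the floor. Its signal of 96 with the miR-429 mimic was not above the 105 of the EpCAM-positive NC antagomir array. The complexes that contain RBBP4 had a median of -0.01 over 27 members (percentile 58.23), the 2 largest being MTA2 (-0.95) and SUDS3 (0.81). The RBBP4 axis had 2 expressed members, RBBP4 and E2F1, with a median of 0.10. POU5F1, a pluripotency factor, was measured only by a probe set shared with its paralog and pseudogenes, which gave signals of 487 and 336.

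The interferon response had a median of -0.17 over 22 members (percentile 7.61). Its members past 2-fold were all lower: IFIT1, an RNA-binding interferon effector (at least 4.6-fold, to a signal under the floor), the 2′-5′ oligoadenylate synthase OAS2 (-1.27) and the RNA sensor RIGI (-1.10). Hypoxia and glycolysis had a median of -0.24 (percentile 13.57), with hexokinase HK2 at 0.98 and the aldolase ALDOC at -0.62 as its 2 largest. Sterol synthesis and uptake had a median of 0.07 (percentile 83.13), the 2 largest being squalene epoxidase SQLE (0.80) and the desaturase SCD (0.75). Hepatocyte genes, of which 15 of 36 were expressed, had a median of 0.00 (percentile 43.96). AMBP, a plasma protein precursor (at least 1.9-fold, to a signal under the floor), and the drug-metabolising enzyme CYP3A4 (-1.05) were lower.

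Among single genes at or above the floor on both arrays, the largest log2 ratios with the mimic belonged to the deubiquitinase MINDY3 (2.21), APCDD1L-DT (2.04), the collagen COL12A1 (2.0), the kinase MTOR (1.98), SEMA5B (1.93), AVPR1B (1.90), the lipase LIPE (1.87), SPN (1.86), the keratin KRT15 (1.85) and CEBPE (1.84). The most negative was that of HES6, a helix-loop-helix regulator of the Hairy/Enhancer of split family, with signals of 55 and 535 (-3.28). It was followed by TNFRSF14-AS1 (-2.27), CEBPZ (-2.10), the ubiquitin ligase subunit FBXO28 (-1.86), the mesodermal factor TBXT (-1.79), the apoptosome protein APAF1 (-1.78), the helicase RECQL5 (-1.76), ZNF358 (-1.76), PTGER1 (-1.73) and the transcription factor USF1 (-1.73). With 1 array under the floor, WDR48 was at least 7.5-fold higher, ANHX at least 6.0-fold and PRR35 at least 5.3-fold. LOC390705 was at least 5.8-fold lower, TM4SF5 at least 5.5-fold and ZNF76 at least 5.2-fold. Against the EpCAM-positive NC antagomir array, WDR48 had signals of 398 and 278 and ZNF76 of 50 and 55, and TBXT and APAF1 changed sign. Of all named mimic values, 12 past 2-fold changed sign there and 44 moved by more than the scatter of genes of like signal, while 24 did neither. Some of these genes were named partly by their antagomir ratio, which uses that same array. The counts are therefore partly set by the naming rule and do not measure robustness. The probe sets of a gene often disagreed: the median over probe sets was 0.14 for SPN, 0.53 for LIPE, -0.43 for FBXO28, -0.37 for RECQL5, -0.57 for PTGER1, -0.55 for TNFRSF14-AS1, 1.30 for MTOR, 1.18 for WDR48, 2.82 for FBN1, 1.86 for CDH2, 0.43 for HK2 and, with the sign turned, 1.22 for APAF1.

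In all, 692 of 13180 expressed genes were at least 2-fold higher with the mimic and 496 were lower. Among the 8130 brighter genes the numbers were 146 and 36. With each array centred on the median of its expressed probe sets, the median log2 ratio of all genes in this comparison moved from -0.002 to -0.11, and the split became 549 higher and 628 lower, 46.6% higher in place of 58.2%. Relative to that shift the medians were 0.36 for NF-kB, 0.52 for the small RNA machinery and 0.22 for tumour-initiating markers, while those of the epithelial (-0.06), mesenchymal (-0.03), mitotic (-0.01) and sterol (-0.04) lists turned negative. Under quantile normalization the hypoxia median was 0.03, that of the RBBP4 complexes 0.06 and that of E2F targets 0.10. The mimic pair also differed in its control probe sets: the poly-A spike-ins were 0.82 log2 units lower and the hybridisation controls 0.46 lower on the miR-429 mimic array, and the actin 3′ to 5′ ratio was 2.63 against 3.41. The log2 ratio increased with the span of the gene on the genome, from a median of -0.24 in the shortest of 5 equal span bins of brighter genes (median span 4.4 kb) to 0.27 in the longest (123.7 kb), with a Spearman rho of 0.38 across genes, which are not independent replicates.

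**Figure D1:**
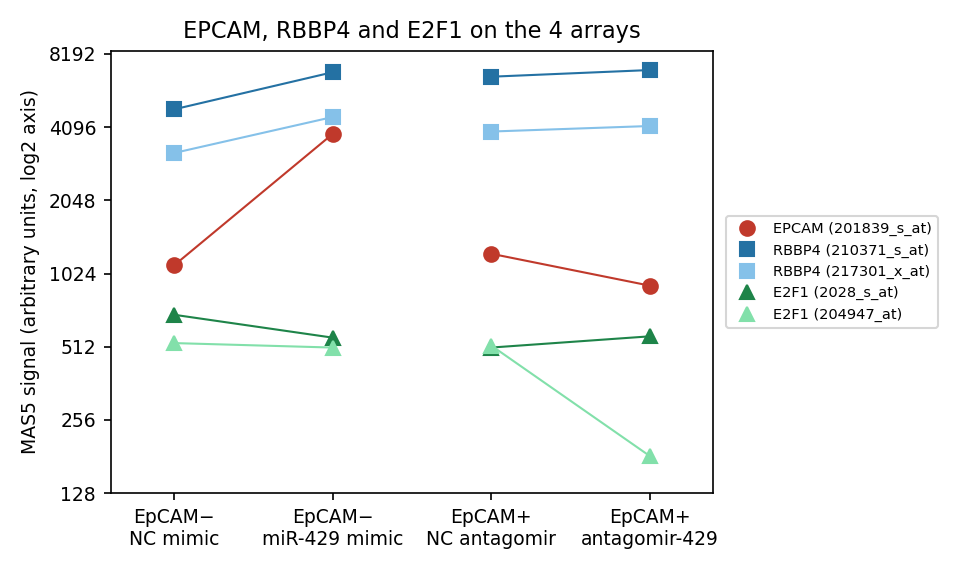
MAS5 signal (arbitrary units, log2 axis) of EPCAM, RBBP4 and E2F1 on the 4 arrays, 1 point per array and probe set, with lines joining a treatment to its control. Of the 5 RBBP4 probe sets past the filter only the 2 brightest are drawn. The probe set that was lower with the mimic (252 against 353) is not among them. EPCAM is at 3838 on the miR-429 mimic array and between 913 and 1235 on the others; the 2 E2F1 probe sets part on the antagomir-429 array, at 565 and 182.

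**Figure D2:**
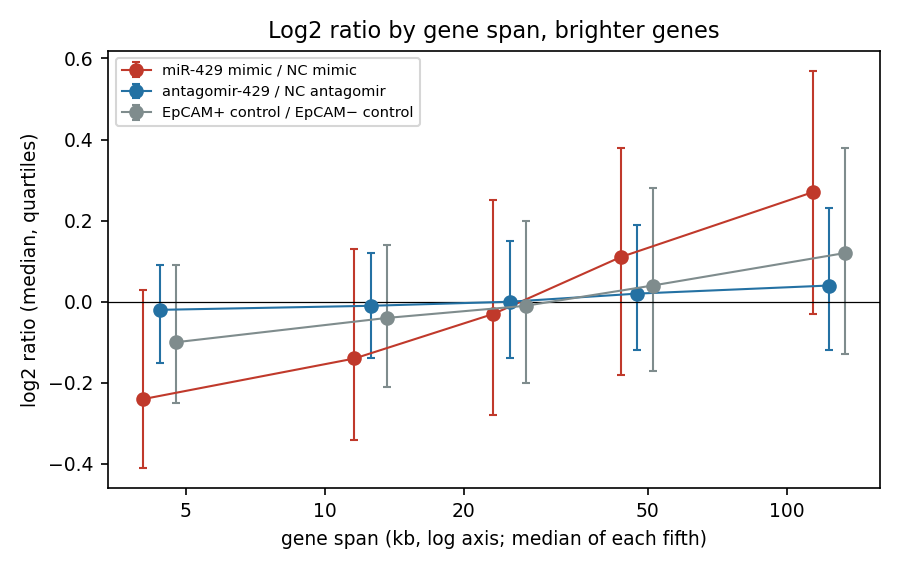
Median log2 ratio (points) and quartiles (bars) of the 8130 brighter genes in 5 equal bins of gene span (kb, log axis), for each comparison, with points shifted sideways for legibility. The mimic comparison runs from -0.24 to 0.27 and the antagomir comparison from -0.02 to 0.04.

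In EpCAM-positive cells fewer bright genes were past 2-fold with antagomir-429 than had been with the mimic in EpCAM-negative cells, and the inflammatory group lay on the other side of 0 from its place with the mimic. NF-kB and inflammatory genes had a median log2 ratio of -0.35 (percentile 0.0 after rounding), with 11 of 16 members below 0. Without the filter on low signals, which lets in 3 dimmer members, that median was -0.08 (percentile 19.28). CCL20, a chemokine, was the only one past 2-fold, at least 2.6-fold lower with the antagomir-429 array under the floor. EPCAM had a signal of 913 with antagomir-429 and 1235 with the NC antagomir, a log2 ratio of -0.44. RBBP4 hardly differed by its brightest probe set, at 7029 and 6599 (0.09), while its dimmest past the filter had 112 and, under the floor, 8, and the published targets of the miR-429 seed had a median of 0.02 (percentile 57.11), which was -0.01 with median centring. The transcription factor TCF7L1 was the only one of these targets past 2-fold, at least 2.2-fold lower with the antagomir-429 array under the floor.

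Apart from NF-kB, 4 more lists lay outside the middle 95% of random lists. Mitotic genes had a median of 0.15 (percentile 99.59) with 0 of 27 past 2-fold. The 2 largest were the proliferation antigen MKI67 (-0.88), whose median over probe sets was 0.15, and the topoisomerase TOP2A (0.85). The small RNA machinery had a median of 0.43 (percentile 99.88), with 8 of 13 members above 0 and 5 below. As in the mitotic list, 0 members were past 2-fold, and the 2 largest were DICER1 (-0.82) and TNRC6B (0.77). Mesenchymal genes had a median of -0.13 (percentile 1.32), although the only one past 2-fold, the gelatinase MMP2, was higher (1.32). Under the stricter filter the mesenchymal median was -0.09 (percentile 5.22). Markers of leukocytes and stroma had a median of -0.42 (percentile 1.38) at dim signals, with VWF at least 1.9-fold higher (signals 102 and 27) and CSF1R at least 1.7-fold lower (signals 42 and 88).

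The other lists lay within that range. Tumour-initiating and pluripotency markers had a median of -0.13 (percentile 2.7), with DLK1 (-0.79) and SOX2 (0.61) as the 2 largest, but lay outside the range in 4 of 7 alternatives, among them the stricter filter (-0.20, percentile 0.14). CDK inhibitors and p53 targets had -0.11 (percentile 5.15), the 2 largest being the BH3 protein PMAIP1 (-0.97) and ZMAT3 (-0.69). Epithelial genes had -0.03 (percentile 27.27), with claudin CLDN4 at -0.88 and the epithelial factor ELF3 at -0.50. E2F targets and DNA replication had 0.04 (percentile 86.3), with cyclin CCNE2 at -0.65 and the phosphatase CDC25A at 0.46. The RBBP4 complexes had 0.00 (percentile 51.41), with SAP30 at -0.38 and CHD3 at -0.34. The interferon response had -0.03 (percentile 30.3), with IFIT2 at least 1.6-fold and IFNL1 at least 1.9-fold higher from signals under the floor. Sterol genes had -0.01 (percentile 44.66), with the sterol carrier STARD4 at least 3.0-fold higher from a signal under the floor and MYLIP, which drives degradation of the LDL receptor, at 1.13. The stress response had 0.04 (percentile 76.39), with CHAC1 at 1.45 and DDIT3, a stress-induced transcription factor, at 1.08. Hypoxia and glycolysis had 0.01 (percentile 61.17), with HK2 at 0.71 and the oxygen sensor EGLN3 at -0.65, and -0.02 with median centring or quantile normalization, and hepatocyte genes had 0.22 (percentile 91.48), with the apolipoprotein APOC3 at least 2.0-fold higher from a signal under the floor. The RBBP4 axis had a median of 0.12 from RBBP4 and E2F1, where the E2F1 probe sets disagreed: the brighter gave 0.15 and the other -1.51, with signals of 182 and 518. The shared POU5F1 probe set gave 239 and 296, and ZEB1 gave 65 and 123.

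Among genes at or above the floor on both arrays, the largest positive log2 ratios with antagomir-429 were those of the guanine exchange factor FGD2 (2.54), TSPAN10 (2.47), ZNF76 (2.25), the glycogen phosphorylase PYGB (2.09), SEMA4D (1.95), the coenzyme Q protein COQ8B (1.87), LOC100506271 (1.78), KLF12 (1.76), GOLPH3L (1.74) and ARHGEF11 (1.73). For FGD2, PYGB and COQ8B it was the NC antagomir array that lay low: FGD2 had a signal of 73 there and between 395 and 508 on the other arrays, PYGB had 105 there and between 395 and 446, and COQ8B had 223 there and between 556 and 813. The most negative among the same genes were those of the peptide hormone INSL3 (-2.45), SBNO2 (-1.96), MYOZ3 (-1.92), ITFG2 (-1.89), NPAT, a coactivator of histone genes (-1.77), the aryl hydrocarbon receptor AHR (-1.76), the bradykinin receptor BDKRB2 (-1.75), SPPL2B (-1.69), ARHGAP27P1 (-1.67) and GDF2 (-1.65). With 1 array under the floor, MIR1-1HG was at least 5.1-fold higher, CRY2 at least 5.0-fold and WFIKKN1 at least 5.0-fold. IGFL2 was at least 7.0-fold lower, SPATA32 at least 5.2-fold and LINC01210 at least 5.2-fold. The median over probe sets was -0.02 for SPPL2B, -0.23 for ITFG2, -0.37 for NPAT, 0.68 for ARHGEF11, 0.81 for KLF12, 1.70 for FGD2, -1.16 for SBNO2, -0.82 for MYOZ3, 0.28 for HK2, -0.13 for EGLN3, -0.10 for CHD3 and, with the sign turned, -0.52 for MYLIP.

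Of the 13180 expressed genes, 490 were at least 2-fold higher with antagomir-429 and 465 were lower, and of the 8130 brighter genes 24 and 15. Most genes past 2-fold were dim: 24.2% of the dimmest of the 4 signal bins passed and 0.0% of the brightest. Control probe sets differed little between these 2 arrays, by 0.08 log2 units for the spike-ins and 0.01 for the hybridisation controls, and the actin 3′ to 5′ ratios were 3.07 and 3.12.

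**Figure D3:**
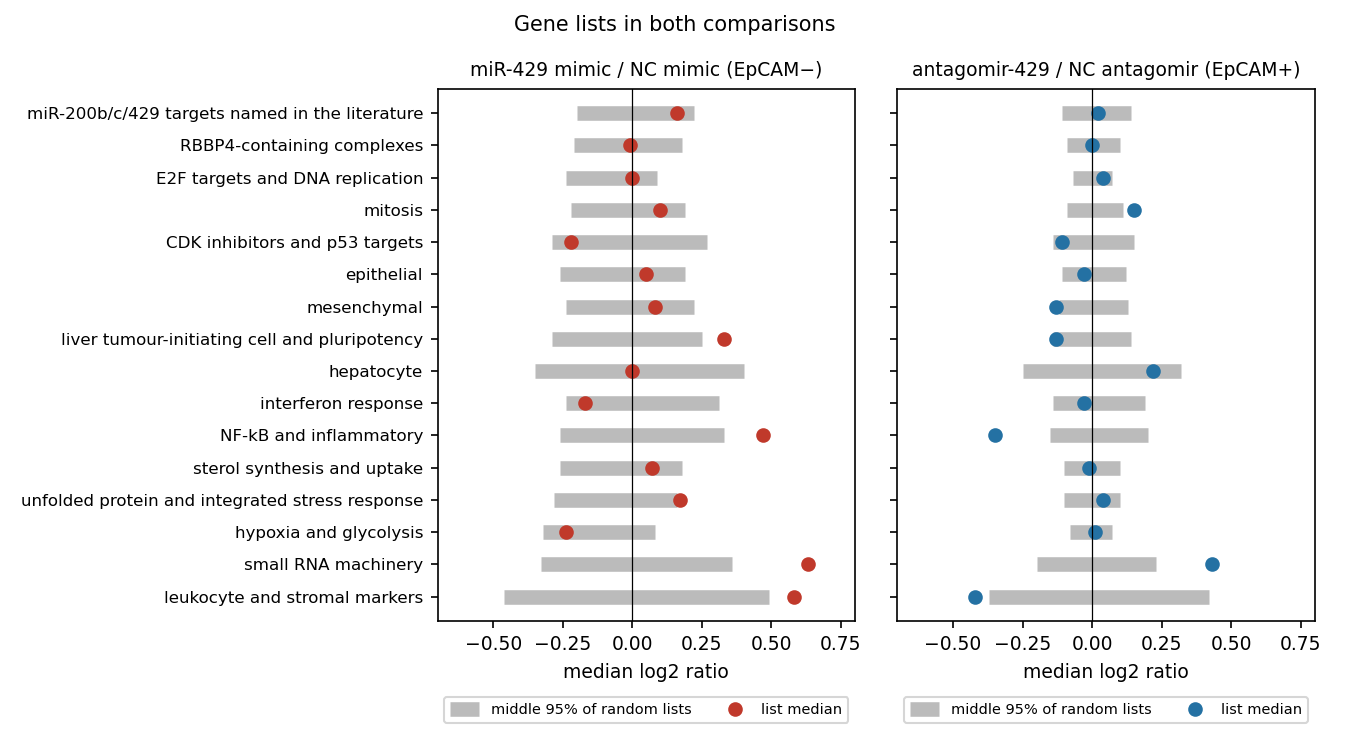
Median log2 ratio of the expressed members of 16 gene lists (points) with the middle 95% of the medians of 10000 random lists matched on signal (grey bars), for the mimic and the antagomir comparison. NF-kB and inflammatory genes lie at 0.47 with the mimic and -0.35 with the antagomir, and the small RNA machinery lies at 0.63 and 0.43.

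Few genes were past 2-fold in opposite directions in the 2 treatments. Lower with the mimic and higher with the antagomir is the pattern sought for targets, but the treatments were given to different sorted fractions. A 2-fold count also leaves out smaller changes. Of changes simulated at exactly 2-fold, 49.5% were counted with the spread of the mimic comparison and 51.0% with that of the antagomir. These shares follow from setting the change at the threshold and say nothing about the spread. A gene had to pass in both treatments to be counted here, so a smaller share would be caught, and that share was not simulated. In total 51 genes were at least 2-fold lower with the mimic and at least 2-fold higher with the antagomir. Those named by the rule were dim, and folds against arrays under the floor are lower bounds. The circadian repressor CRY2 was at least 2.9-fold lower and at least 5.0-fold higher, BTBD2 at least 4.2-fold and 3.0-fold, OR13C4 at least 3.3-fold and 3.2-fold, and ESF1 at least 2.2-fold and 2.5-fold. The zinc finger protein ZNF76 was at least 5.2-fold lower with the mimic and had a log2 ratio of 2.25 with the antagomir. For the potassium channel subunit KCNG2 (at least 3.6-fold and 1.6-fold), SAMSN1 (3.1-fold and 1.7-fold), GLYATL1-AS1 (1.8-fold and 2.5-fold) and TSPAN10 (1.9-fold, then a log2 ratio of 2.47), a bound was under 2-fold. SEPSECS was at least 2.8-fold lower and 3.3-fold higher by its brightest probe set, but its medians over probe sets were -0.37 and 0.62, short of 2-fold in both. The converse held for 44 genes, among them TSSK2, OR10J1, the guidance ligand SLIT2, the glucose-responsive factor MLXIPL, BDKRB2, VPS13B, ESRRB, C5AR1, C6orf15 and ATOH7. TSSK2 was at least 2.5-fold higher and at least 2.5-fold lower, and ATOH7, the last of these by rank, was at least 2.8-fold higher with the mimic and had a log2 ratio of -1.50 with the antagomir. A bound was under 2-fold for MLXIPL and C5AR1 with the mimic (at least 1.7-fold each) and for SLIT2 with the antagomir (at least 1.9-fold). For each of these 20 genes at least 1 of the 4 arrays lay under the floor of 52.9. With arrays under the floor raised to it, a count added after the data were seen, 23 of the 51 genes and 20 of the 44 were past 2-fold in both treatments. With the EpCAM-positive NC antagomir array as the mimic's control, MLXIPL (-0.74) and C5AR1 (-0.83) turned to lower. TSSK2, ESRRB, BDKRB2, VPS13B and ATOH7 lay near 0, and OR10J1, SLIT2 and C6orf15 were higher by less than 2-fold. For CRY2, KCNG2, SAMSN1, BTBD2, ESF1, OR13C4, SEPSECS and GLYATL1-AS1 both signals were under the floor and gave no direction. ZNF76 and TSPAN10 were short of 2-fold against the floor. Thus none of these 20 genes was past 2-fold there against the floor. That array is also the antagomir's control, so this check is not independent of how the genes were chosen.

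If the 2 sets of genes were independent, 18.4 genes would be lower then higher and 24.4 higher then lower. Matching on signal, which lets dim genes pass by scatter in both pairs, raised these expected numbers to 54.4 and 62.0, above the observed 51 and 44. Differences in the same direction were more frequent, with 71 genes higher in both (63.3 expected within signal bins) and 64 lower in both (53.7 expected). Across all expressed genes the 2 log2 ratios had a Pearson r of 0.07 and a Spearman rho of 0.11, and across the brighter genes both were 0.19. Among brighter genes 0 were lower then higher, 0 were higher then lower, 3 were higher in both and 1 was lower in both.

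The control arrays compare EpCAM-positive cells given NC antagomir with EpCAM-negative cells given NC mimic, so the sorted fraction and the control treatment differ together and cannot be told apart. EPCAM had nearly the same signal in both, 1235 in EpCAM-positive and 1106 in EpCAM-negative cells (log2 ratio 0.16). The mRNA of the sort marker thus did not separate these 2 arrays, so the labels of the sorted fractions have no check in it, and EpCAM-positive and EpCAM-negative are used here as the labels give them. Hypoxia and glycolysis genes were lower in the EpCAM-positive control, with 17 of 19 members below 0 and a median of -0.48 (percentile 0.0 after rounding). NF-kB and inflammatory genes were lower too, with 13 of 16 below 0 and a median of -0.49 (percentile 0.01). Mitotic genes were lower with a median of -0.19 (percentile 0.92). These 2 arrays also differed in their control probe sets, by -0.43 log2 units for the poly-A spike-ins and -0.22 for the hybridisation controls, with actin 3′ to 5′ ratios of 3.12 and 3.41, and across the brighter genes the log2 ratio had a Spearman rho of 0.21 with gene span.

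In the hypoxia list, the members past 2-fold were the lipase inhibitor ANGPTL4 (-1.28), the collagen prolyl hydroxylase P4HA1 (-1.07) and the enolase ENO2 (-1.01). In the NF-kB list they were the chemokines CXCL8 (-1.96) and CXCL3 (-1.03), and in the mitotic list TOP2A (-1.31), the hyaluronan receptor HMMR (-1.28) and the spindle motor KIF11 (-1.07). The small RNA machinery was higher, with a median of 0.31 (percentile 98.82) and AGO3 at least 2.2-fold higher from a signal under the floor, and lay at percentile 94.02 with the median over probe sets. The published targets of the miR-429 seed had a median of 0.15 (percentile 98.06), although the 2 members past 2-fold were lower: the TGF-beta receptor TGFBR1 (-1.19) and the leptin receptor LEPR (at least 1.9-fold, to a signal under the floor). After subtraction of the trend with gene span that median was 0.10 (percentile 94.03), within the range of random lists.

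The remaining lists lay within the middle 95% of random lists, the interferon response at its edge: its percentile was 2.81, and 2.33, outside the range, with a second draw of random lists. Epithelial genes had a median of -0.09 with TJP1 at 1.43, and mesenchymal genes 0.11 with FBN1 at 1.33, MMP2 at -1.29, the integrin ITGA5 at -1.13 and TGFB1 at -1.07. Tumour-initiating markers had 0.16, with CD24 (0.83) and DLK1 (0.69) as the 2 largest. Medians were 0.09 for the RBBP4 complexes, 0.06 for E2F targets and DNA replication, -0.18 for CDK inhibitors and p53 targets with CDKN2B at least 2.0-fold higher from a signal under the floor, -0.18 for hepatocyte genes and -0.22 for the interferon response with IFIT2 at least 1.8-fold lower. They were -0.15 for sterol genes with STARD4 at least 2.0-fold lower, both to signals under the floor, -0.13 for the stress response and 0.29 for markers of leukocytes and stroma. RBBP4 had a log2 ratio of 0.45 and E2F1 of -0.45, ZEB1 of 0.62 at dim signals, and the shared POU5F1 probe set of -0.18.

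Among single genes at or above the floor on both control arrays, the EpCAM-positive control was highest over the EpCAM-negative one for CCDC157 (2.40), the adhesion protein NECTIN1 (1.98), ASMTL-AS1 (1.90), the glutamate receptor subunit GRIN1 (1.82), CRTC1 (1.81), the endocytic scaffold ITSN1 (1.79), the chromatin cofactor HCFC1 (1.79), PTPN21 (1.77), CROCC (1.75) and CCNP (1.74). It was lowest for CCDC24 (-2.74), FGD2 (-2.44), ZNF76 (-2.30), COL11A2 (-2.10), BTNL3 (-2.07), the ETS factor SPDEF (-2.04), MTF2 (-2.03), CXCL8 (-1.96), APC2 (-1.95) and PYGB (-1.91). For ITSN1 (signal 142) and HCFC1 (213) the NC mimic array alone lay low against the other 3, and for FGD2 and PYGB the NC antagomir array alone did. With 1 of these arrays under the floor, CLCN6 was at least 7.8-fold higher, WDR48 at least 5.3-fold and ZNF532 at least 4.8-fold, while WFIKKN1 was at least 7.3-fold lower, CHRNB2 at least 7.2-fold and NPM2 at least 6.9-fold. The median over probe sets was under 2-fold for CCDC157 (0.40), ITSN1 (0.41), PTPN21 (0.29), TJP1 (0.18), WDR48 (0.18), ASMTL-AS1 (0.75), CROCC (0.57), SPDEF (-0.72), MTF2 (-0.85), TGFB1 (-0.52), IFIT2 (-0.76) and ANGPTL4 (-0.88). It was -1.25 for FGD2, 1.83 for ZNF532, 2.23 for FBN1 and 0.52 for CD24. In all, 477 of 13180 expressed genes were at least 2-fold higher and 619 lower, and 60 and 60 of the brighter ones. Over the 3 comparisons 48 list percentiles were computed, of which 15 lay outside the middle 95%, or 16 with a second draw of random lists. If the 48 were independent, 2.4 would by chance. They are not, since lists share genes and this comparison shares an array with each of the others, so these counts are not a test.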

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

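The count of unnamed probe sets follows a rule that was set in advance, and no test in this part was chosen only after the result was seen. No group had the 4 samples that an outlier check needs, and no contrast was run in more than 1 kind of cell.

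Probe sets without a gene name stood outside all of the comparisons of genes and were looked at separately. Of 11721 such probe sets, 815 passed the stricter filter. Among these, 15 were at least 2-fold higher with the miR-429 mimic than with the NC mimic and 10 were lower. With antagomir-429 6 were higher and 4 were lower. No explanation was tested for them.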

How the results depend on the processing

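The alternatives with the gene span trend subtracted and with the EpCAM-positive NC antagomir array as control were chosen only after the result was seen. Without the filter, genes past 2-fold numbered 2539 higher and 2248 lower with the mimic, 2226 and 2412 with the antagomir, and 2264 and 2539 between the controls, with 528 lower then higher, 593 higher then lower and 1139 in the same direction in both treatments. The stricter filter left 146 and 36, 24 and 15, and 60 and 60, with 0, 0 and 4, and the correlation across genes was 0.19 in place of 0.07. Fewer or more genes tested, and more of them dim, follow from how these filters are built. At 1.5-fold the counts were 1911 and 1439, 1232 and 1093, and 1362 and 1580, with 215, 200 and 552. The offset, which shrinks differences of dim genes, gave 33, 29 and 85. The other counts over expressed genes stayed within 1.5 times their value as deposited under centring, quantile normalization, the median over probe sets, the offset and, where run, the added alternatives. The span trend subtracted gave 626 and 530 with the mimic, but among brighter genes 89 and 59 in place of 146 and 36. The EpCAM-positive NC antagomir array as control gave 706 and 426, and 105 and 35 among brighter genes; it was not used for the comparison of both treatments, which would then share an array. The median of the published targets stayed between 0.05 and 0.18 with the mimic and between -0.07 and 0.03 with the antagomir, where its sign was not fixed. With the median over probe sets, APAF1 turned to 1.22 with the mimic and MYLIP to -0.52 with the antagomir; the cause was not tested. E2F1 went from 0.15 to -0.68 with the antagomir there, and MKI67 from -0.88 to 0.15, or to 0.07 with the offset. With the EpCAM-positive NC antagomir array as control, 12 named mimic values that were past 2-fold changed sign. CRY2, KCNG2, SAMSN1, MLXIPL, BDKRB2, VPS13B, C5AR1 and ATOH7 were named partly by an antagomir ratio that uses that array. The naming rule therefore favours a change of sign for them, and no other cause was tested. For CRY2 (1.16), KCNG2 (0.93) and SAMSN1 (1.09) both signals lay under the floor, so no direction was measured, and for TBXT (1.52) and APAF1 (0.37) that control did. The others went, MLXIPL to -0.74, BDKRB2 to -0.05, VPS13B to -0.01, C5AR1 to -0.83, ATOH7 to -0.08, CDKN2B to -0.13 and TJP1 to -0.07. ALDOC, short of 2-fold, went from -0.62 to 0.06. In all, 1318 named values held, 91 moved and 14 turned, where held means a change within the robust SD of genes of like signal. Of those held, 214 without the filter and 59 under the stricter filter could not change, because a gene keeps its brightest probe set. Centring, which shifts all genes of an array alike, left all 214 within the SD. Under that control 24 held, 44 moved and 12 turned. Of list medians 329 held and 5 moved, where held means inside the middle 95% of medians of resampled list members. These intervals were wide. NF-kB with the antagomir counted as held at -0.08 without the filter (interval -0.61 to 0.08). The small RNA machinery with the mimic counted as held at 0.23 under that control (interval 0.05 to 0.96). Those that moved were hypoxia with the mimic under centring (-0.35), and under that control hypoxia, turned to 0.48, NF-kB (1.08), sterol (0.29) and tumour-initiating markers (0.07). Of the 15 lists outside the middle 95% of random lists, 14 stayed outside after the span trend was subtracted. Of 8 alternatives, 2 brought the tumour-initiating list with the mimic inside, among them no filter (0.18, percentile 91.33), 4 the stress response and 1 the small RNA machinery. Of 7, 2 brought the leukocyte list with the mimic inside, 3 the mesenchymal and 1 the NF-kB list with the antagomir, and 3 the published targets and 2 the small RNA machinery between the controls. Lists brought outside included hypoxia, mitosis and sterol with the mimic under that control, and tumour-initiating markers with the antagomir in 4 of 7, and in 1 setting each CDK inhibitors with the mimic and between the controls, hypoxia with the antagomir, and sterol and stress response genes between the controls. No paired analysis was possible because each group had 1 array, and leaving out a replicate was not possible for the same reason. The search for seed sites and its alternatives were not run, since UTR sequences were not used here. Signal over background limits all counts: 24.9% of the dimmest of the 4 signal bins passed 2-fold with the mimic and 0.6% of the brightest.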

Other observations

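The search for genes apart from all other arrays, the EpCAM-positive NC antagomir array as control, and the tests on the NC mimic array, on mixed cells and on the EPCAM probe set, were chosen only after the result was seen; those on gene span and on single NF-kB members were set after the data were seen but before their own results.

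Genes that lay at least 2-fold from all 3 other arrays were looked for among the 8130 brighter genes, and the genes named in this paragraph and the next were chosen after their values were seen. On the miR-429 mimic array 6 lay above all others: EPCAM by 1.64 log2 units, the long non-coding RNA UCA1 by 1.37, the adaptor protein SASH1 by 1.16, LCN2 by 1.11, TNFAIP3 by 1.08 and LINC02846 by 1.04. On the same array 7 lay below all others, the furthest being the aldo-keto reductase AKR1C2 at -1.66, with a signal of 317 against 999 to 1075 elsewhere; the AKR1C genes are close in sequence and their signals are uncertain to assign. The next were FBXO28 (-1.48), MIR1915HG (-1.22) and the hexosaminidase HEXD (-1.21).

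On the antagomir-429 array 0 lay above and 5 below: INSL3 (-1.85), the histamine receptor HRH1 (-1.53), the keratin KRT16 (-1.31), the endolysosomal channel TPCN1 (-1.10) and EFHC2 (-1.07). The NC antagomir array had 0 above and 4 below, FGD2, PYGB, COQ8B and SAMD4A. The NC mimic array had 1 above, COPS2, and 25 below, among them the chromatin regulators TET3 (-1.41), HCFC1 (-1.42) and ARID1A (-1.14), and also TJP1 (-1.37) and FBN1 (-1.20).

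Of the brighter genes 146 were 2-fold higher with the mimic and 36 were lower, and no technical explanation for this was excluded. A low NC mimic array cannot be told apart as the cause. The number of genes under all 3 other arrays on it, 25, was 4.17 times the 6 over all others on the miR-429 mimic array, but with the EpCAM-positive NC antagomir array as control 105 brighter genes were still higher and 35 lower, and that control differs in sorted fraction and treatment as well. A trend with gene span cannot be told apart either: its subtraction left 89 higher and 59 lower, a ratio of 1.51, where at most 1.5 would point to it and 3 or more would exclude it. An effect of miR-429 itself stays open as untested.

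EPCAM was higher with the mimic. Gene span was argued against as a technical explanation, and the others were tested only in part. EPCAM lay 1.64 log2 units above the highest other array. The NC mimic signal of 1106 was not low against the EpCAM-positive arrays (1235 and 913). Whether it was low for its own fraction cannot be told apart. The nearest array was the EpCAM-positive NC antagomir one, so mixed-in cells with EPCAM at that array's level do not account for the difference. That check rests on the same 1.64, and mixed-in cells with more EPCAM were not tested. After subtraction of the span trend the log2 ratio was 1.86. Another transcript binding the probes cannot be told apart, because 1 probe set measures EPCAM and no second exists to compare. A deviation of the miR-429 mimic array itself was not tested either. That array had the lowest mean log2 signal of the poly-A spike-ins (11.35) and of the hybridisation controls (13.05), and the lowest actin 3′ to 5′ ratio (2.63). Drift in culture, a mix-up of samples and an effect of miR-429 were not tested and stay open, the more so as EPCAM did not separate the 2 control arrays.

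NF-kB and inflammatory genes were higher with the mimic and lower with the antagomir; relative to the mean of the 4 arrays, the list median was 0.21 on the NC mimic, 0.73 on the miR-429 mimic, -0.26 on the NC antagomir and -0.52 on the antagomir-429 array. Gene span was argued against, with a mimic median of 0.58 after subtraction of the trend (random lists -0.25 to 0.3), and without the 3 largest members the median was 0.39, narrowly above random lists (-0.3 to 0.37). The NC mimic array was not low against the other arrays: it was the lowest for 1 of 16 members, while the miR-429 mimic array was the highest for 15. Whether it was low for its own fraction cannot be told apart. The median over the EpCAM-positive control was 1.08 (random lists -0.2 to 0.29), but that control was itself lower than the NC mimic array (-0.49), with fraction and treatment confounded. Culture conditions of single samples, a deviation of the miR-429 mimic array itself and an effect of miR-429 were not tested and stay open. Without the filter on low signals the antagomir median was -0.08.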
